A study of Drosophila melanogaster with 3 samples.

How the data were processed

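The study hybridised genomic DNA from salivary glands of roaming larvae (2 biological replicates) and from ovaries (1 sample) with a common reference of embryo DNA on a custom Agilent array. Tissue DNA was labelled with Cy5 and embryo DNA with Cy3 on all 3 arrays, with no dye swap, per the labels. The deposited scanner files hold intensity values per spot, which Feature Extraction made by subtracting background, detrending and normalising the dyes, per the file headers. The deposited scanner files also hold a log10 ratio of the processed signals and flags of 0 or 1 (other values), per the file headers. The deposited series table holds log2 values per probe, which the authors made with limma per the submitters' processing notes, and the version and settings are not given in the sources used here. The direction and scale of that table were checked against the scanner values, with r = 0.877, 0.968 and 0.960 and slopes of 0.983, 1.04 and 1.03 for the ovary and salivary gland replicates 1 and 2. The level at which the authors centred it is not given in the sources used here.

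Each array held 105072 spots with 1325 controls, and 1.06%, 1.18% and 1.13% of the other spots were left out as outliers by the scanner's own flags. The median raw signal over all spots was 645 in Cy3 and 526 in Cy5 on the ovary array, 760 and 960 on salivary gland array 1 and 854 and 1327 on salivary gland array 2, against background medians of 28 to 38.5. The ratio log2 of Cy5 over Cy3 was taken from the processed signals, spots of 1 probe were averaged, and each array was centred on its median probe. After this step the distal arms sat at 0.08, 0.10 and 0.11 on the ovary and salivary gland arrays, since many repeated sequences lie among the probes. Differences from the arms are therefore given for the assembled heterochromatin, chromosome 4, the X, and the housekeeping and ribosomal protein genes. Most other ratios are given as centred on the median probe. Probe positions are those of genome Release 5 as the array files give them. No genome or annotation of that release was at hand, so genes are the names in the array files, matched to current symbols where possible (20392 of 23447 gene probes). This replaces the planned assignment of probes to genes by position. A gene with probes on several scaffolds was split by scaffold. A minimum of 5 probes gave 1645 of 7859 windows of 10 kb, of which 1637 had values on all arrays, and a minimum of 3 probes gave 1392 of 15941 genes, of which 1390 had such values. Gene lists were set with every gene with at least 1 probe (15919 with values on all arrays), as were the highest genes of the salivary gland, the Y genes and the ovary genes.

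Window and gene means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, a mean per tissue, all 3 arrays, 1 residual degree of freedom), two-sided, with Benjamini-Hochberg adjustment. A call needed an adjusted p under 0.05 and a log2 ratio of at least 0.5 in size. In the window fit the prior degrees of freedom were infinite, so that every window shared a pooled standard deviation of 0.0734. The ovary array, without replicate, was assumed to vary like the salivary gland arrays. Tests against the embryo DNA are tests of the ratio against 0. The ovary and salivary gland replicate 1 lay on 1 slide and replicate 2 on another. A slide term leaves 0 residual degrees of freedom, so the difference within the shared slide is given with no test. Region medians were planned as descriptions and were not tested. Medians of 10 gene lists were set against 10000 rotations of the gene order along the genome, a permutation test that keeps neighbours together, adjusted over 20 tests (both tissues). The smallest p it can give is 0.0002.

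The lists were Y chromosome genes, pericentromeric genes of chromosomes 2, 3 and X, chromosome 4 genes, chorion and eggshell genes, Hox complexes, replication-dependent histone genes, housekeeping genes and glue genes. Lists, tests, alternatives and the rule for named genes were chosen before the data were examined, except for the additions named here and in the closing section. The count of ovary genes called against embryo DNA was such an addition. The rule names from each list the lowest and the highest member in the salivary gland and every called member of lists with at most 4. It adds the 10 lowest and 10 highest called genes and the 10 largest differences between tissues in each direction, the 5 longest stretches of called windows, and the 5 highest and 5 lowest ovary windows. Examples of further list members, of stretches and of genes with 1 or more probes were chosen after their values were seen. So were the windows of 100 kb, the satellites, the bins of embryo signal and the contig series. A probe was assigned to a satellite when its repeat covered at least 70% of the probe. Stretches joined called windows across at most 1 window that was not called.

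The fits were tested on simulated data with 200 added changes. The alternatives were centring on the distal arms, normexp background correction with and without loess, the authors' values, filters on dim and on shared probes, windows of 5 and 20 kb, minimums of 3 and 10 probes, a size of 1, the median of probes, probes as units, other minimums per gene and leaving out each salivary gland replicate. Other work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.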

Results

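Genomic DNA of larval salivary glands and of adult ovaries was compared with embryo DNA on 3 dual-colour microarrays. Both tissues hold polytene cells, whose chromosomes are replicated many times without division. All animals were of the Oregon R strain. Salivary glands from roaming larvae of the last instar gave 2 biological replicates, and ovaries enriched for egg chambers of stage 10 gave 1 array. Tissue DNA carried Cy5, and DNA of embryos aged 0 to 8 h carried Cy3 on every array. Each array held 105072 spots, and 83472 probe names remained after control spots were left out. Of these probes, 23447 stood for genes and 60025 carried contig names in 5 series (contig, nw, ru, R and V), whose origin is not given in the sources used here. Spots well above background in the embryo channel made up 98.7% on the ovary array, 97.7% on salivary gland array 1 and 98.2% on salivary gland array 2. In the tissue channel these shares were 98.0%, 98.5% and 99.0%, and 0 spots were saturated. The number of arrays limits the precision. The ovary has no replicate, so its values carry no spread of their own.

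The first comparison asks which sequences are under- or over-represented in polytene salivary gland DNA. Values are log2 ratios of tissue over embryo DNA, given for the salivary gland as mean ± SD of the 2 arrays. The assembled heterochromatin of chromosomes 2, 3 and X lay at -1.07 ± 0.01 (n = 2, 375 probes), and the distal parts of the 5 large arms lay at 0.11 ± 0.01 (n = 2, 21855 probes). The difference was -1.18 ± 0.00 (n = 2), far beyond the spread between the replicates. It was -0.43 (n = 2) after loess, a correction of the ratio for spot brightness. The heterochromatin of the right arm of chromosome 3 lay lowest of the placed scaffolds of the autosomes, at -1.67 ± 0.30 (n = 2), and those of 2R and 3L lay at -1.20 ± 0.01 and -1.10 ± 0.02 (n = 2). After loess these 3 became -1.03, -0.36 and -0.37. The heterochromatin of 2L lay at -0.46 ± 0.09 (n = 2) but at 1.44 after loess, and that of the X lay at -0.02 ± 0.10 (n = 2). Region medians were described, as planned, and not tested.

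**Figure D1:**
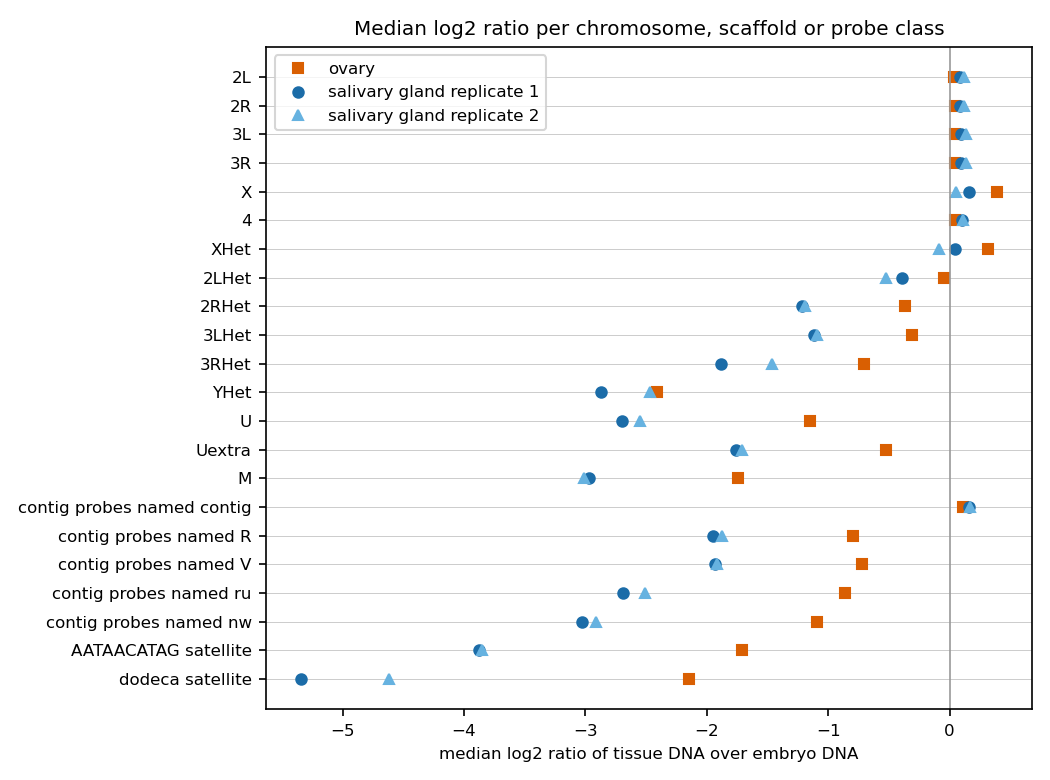
Median log2 ratio of tissue over embryo DNA (x axis) for each chromosome, scaffold or probe class (y axis), with 1 point per array. The 5 large arms and chromosome 4 lie near 0.10 in the salivary gland, and most heterochromatin, unplaced scaffolds and satellites lie below -1 there. After loess the medians of 2LHet, Uextra and the mitochondrial genome turn positive in the salivary gland.

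Next to the assembled heterochromatin the arms differed. In the proximal 1 Mb of 3L the salivary gland median was -0.50 ± 0.02 (n = 2), and -0.19 after loess, and in that of 2L it was -0.09 ± 0.03 (n = 2), and 0.11 after loess. The proximal 1 Mb of 2R lay at 0.05 ± 0.03 (-0.04 in the authors' values) and that of 3R at 0.11 ± 0.04 (n = 2), within 0.1 of the distal arms. Chromosome 4, a short chromosome rich in heterochromatin marks, lay at 0.10 ± 0.01 (n = 2, 234 probes), and its difference from the distal arms was -0.00 ± 0.00 (n = 2). Of its 117 genes with at least 1 probe 10 were called lower and 1 higher in the salivary gland. The window of Rnf11 was called lower at -0.65 ± 0.06 (n = 2), but stood at -0.43 in the ovary too. None of the 25 measured genes of the chromosome 4 list was called there. Its lowest member, zfh2, stood at -0.18 ± 0.58, with 0.23 in replicate 1 and -0.59 in replicate 2, and its highest, dati, at 0.26 ± 0.04 (n = 2). The median of the list was 0.13 (rotation test, adjusted p = 0.759).

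Repeated sequences stood lowest. The dodeca satellite, a tandem repeat near the centromere of chromosome 3, had 3285 probes with a salivary gland median of -4.98 ± 0.51 (n = 2), and all 3285 were called lower. The AATAACATAG satellite had 42 probes at -3.86 ± 0.01 (n = 2), all 42 called lower. Among contig probes, those of the nw series lay at -2.97 ± 0.08 (n = 2), with 10954 of 13420 called lower (81.6%), and those of the R series lay at -1.91 ± 0.05 (n = 2). After loess these medians became -0.52 and -0.08, and the 2 satellites became -2.09 and -0.73. The contig series itself lay at 0.16 ± 0.01 (n = 2), and at -0.14 in the authors' values. Contig probes with an embryo signal over 32 times the median of distal arm probes had a salivary gland median of -4.30 ± 0.42 (n = 2), and those under 0.5 times had 0.21 ± 0.02 (n = 2).

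Genes of the pericentromeric list of chromosome 3 fell in salivary gland DNA for 10 of 19 measured entries (10 also when adjusted over the list alone). The rotation test of the list median (-1.04) gave an adjusted p of 0.014. All 10 lay among the 14 entries placed in heterochromatin, the proximal 1 Mb of an arm or unplaced scaffolds, whose median was -2.20. Snap25, a synaptic membrane fusion protein, lay at -3.14 ± 0.02, nvd, an enzyme of ecdysone synthesis, at -2.66 ± 0.13, and scro, a homeobox gene, at -1.94 ± 0.06 (n = 2, adjusted p = 2.93e-06, 6.43e-06 and 1.19e-05). Snap25 and nvd lie on the proximal arm of 3L and scro in its assembled heterochromatin. Set1 and Dbp80 lie in that heterochromatin too, and they stood at 0.14 ± 0.01 and 0.15 ± 0.06 (n = 2) without a call. On the unplaced scaffold U the part of Pzl fell furthest of all genes with at least 3 probes, to -4.67 ± 0.04 (n = 2, adjusted p = 1.99e-06), and the part of Myo81F there stood at -4.15 ± 0.29 (n = 2), with -3.30 ± 0.35 for its part in the heterochromatin of 3R. SNCF, on 3L outside that heterochromatin, was the highest entry at 0.28 ± 0.13 (n = 2). CR41610 on scaffold Uextra lay at -3.32 ± 0.08 (n = 2), but at 0.54 after loess, and CG41520 on U lay at -3.21 ± 0.03 (n = 2).

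Of the 20 measured pericentromeric genes of chromosome 2, 3 fell (3 adjusted over the list alone). They were uex at -1.05 ± 0.13, Ir41a at -0.83 ± 0.12 and tsh at -0.55 ± 0.04 (n = 2), of which uex stood at 0.58 after loess. The call of tsh ended with normexp (-0.37), after loess (-0.44) and in the authors' values (-0.43). The genes rl, lt and Nipped-A, long known from heterochromatin, stood at 0.03 ± 0.03, 0.19 ± 0.04 and 0.23 ± 0.02 (n = 2), and cta was the highest at 0.32 ± 0.05 (n = 2). The median of this list was 0.10 and its rotation test gave an adjusted p of 1. Of the 8 measured genes of the pericentromeric list of the X, only 4 lay in its heterochromatin or proximal 1 Mb, and 0 of these were called. Outside that region shakB, a gap junction gene, fell to -0.50 ± 0.14 (n = 2), and the call ended with normexp background correction (-0.36) and after loess (-0.22). Grip84, also outside it, was the highest of the list at 0.49 ± 0.19 (n = 2), and the list median of 0.08 gave an adjusted p of 0.887 in the rotation test. Of the 12 measured entries for Y chromosome genes, 11 fell (11 adjusted over the list alone), with a list median of -3.06 (rotation test, adjusted p = 0.001, where the unadjusted p of 0.0002 is the smallest the rotations can give), which became -1.87 with normexp and -1.41 after loess. PRY was the lowest at -4.41 ± 0.43, and kl-2, a dynein gene of sperm, stood at -3.23 ± 0.34 (n = 2). In the ovary, from females without a Y, PRY stood at -4.405, kl-2 at -3.73 and the list median at -3.68. The salivary gland values were thus about as low as those of a tissue without a Y. They do not measure how many Y copies the gland holds, and the sex of the larvae is not given. Pp1-Y1 was not called at -0.11 ± 0.72 (n = 2), with -0.62 in replicate 1 and 0.40 in replicate 2.

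The tandem histone genes fell for all 5 measured members (5 adjusted over the list alone), with a median of -1.65, but after loess all 5 stood above 0, with a median of 1.99. His4:CG31611 was the lowest at -1.89 ± 0.13 and His1:CG31617 the highest at -1.48 ± 0.04 (n = 2). The rotation test of this list gave an adjusted p of 0.0969. The mitochondrial genome was also lower, at -2.99 ± 0.03 (n = 2, 29 probes), but at 0.62 after loess. ND5 and COX1, subunits of the respiratory chain, stood at -3.18 ± 0.07 and -3.01 ± 0.07 (n = 2, adjusted p = 4.45e-06 for both), and after loess at -0.20 and 1.01. ND4, COX3 and LD48059 stood at -3.04 ± 0.10, -2.87 ± 0.04 and -2.21 ± 0.04 (n = 2), and all 3 stood above 0 after loess.

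In windows of 100 kb, chosen after the data were seen, 73 of 1148 were lower in the salivary gland. On the 5 large arms 39 of 1088 were lower and 1 was higher, and the lower ones formed 27 stretches of up to 300 kb. On 2L the stretch from 16900001 to 17200000, with the axon guidance genes beat-IIIa, beat-IIIb and beat-IIIc and the taste receptor genes Gr36a, Gr36b and Gr36c, lay at -1.55 ± 0.10 (n = 2). The stretch on 2L from 14700001 to 15000000, which holds CG15279 and side-II, lay at -0.93 ± 0.14 (n = 2). On 3R the stretch from 12500001 to 12800000 covers the abdominal Hox genes abd-A and Abd-B and lay at -0.94 ± 0.01 (n = 2). These 2 genes fell to -1.07 ± 0.03 and -0.88 ± 0.04 (n = 2, adjusted p = 0.000107 and 0.00027), while the neighbouring Ubx stood at 0.06 ± 0.10 (n = 2). Dfd was the highest of the list at 0.09 ± 0.14 (n = 2). The other 10 genes of the Hox list did not pass (2 of 12 lower, also adjusted over the list alone), and the rotation test gave an adjusted p of 0.217. Of 12710 genes of the autosomal arms with at least 1 probe, 455 were called lower. Only part of these were also lower than in the ovary, and some were low in the ovary against embryo DNA too. Not all of them are therefore particular to the salivary gland.

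**Figure D2:**
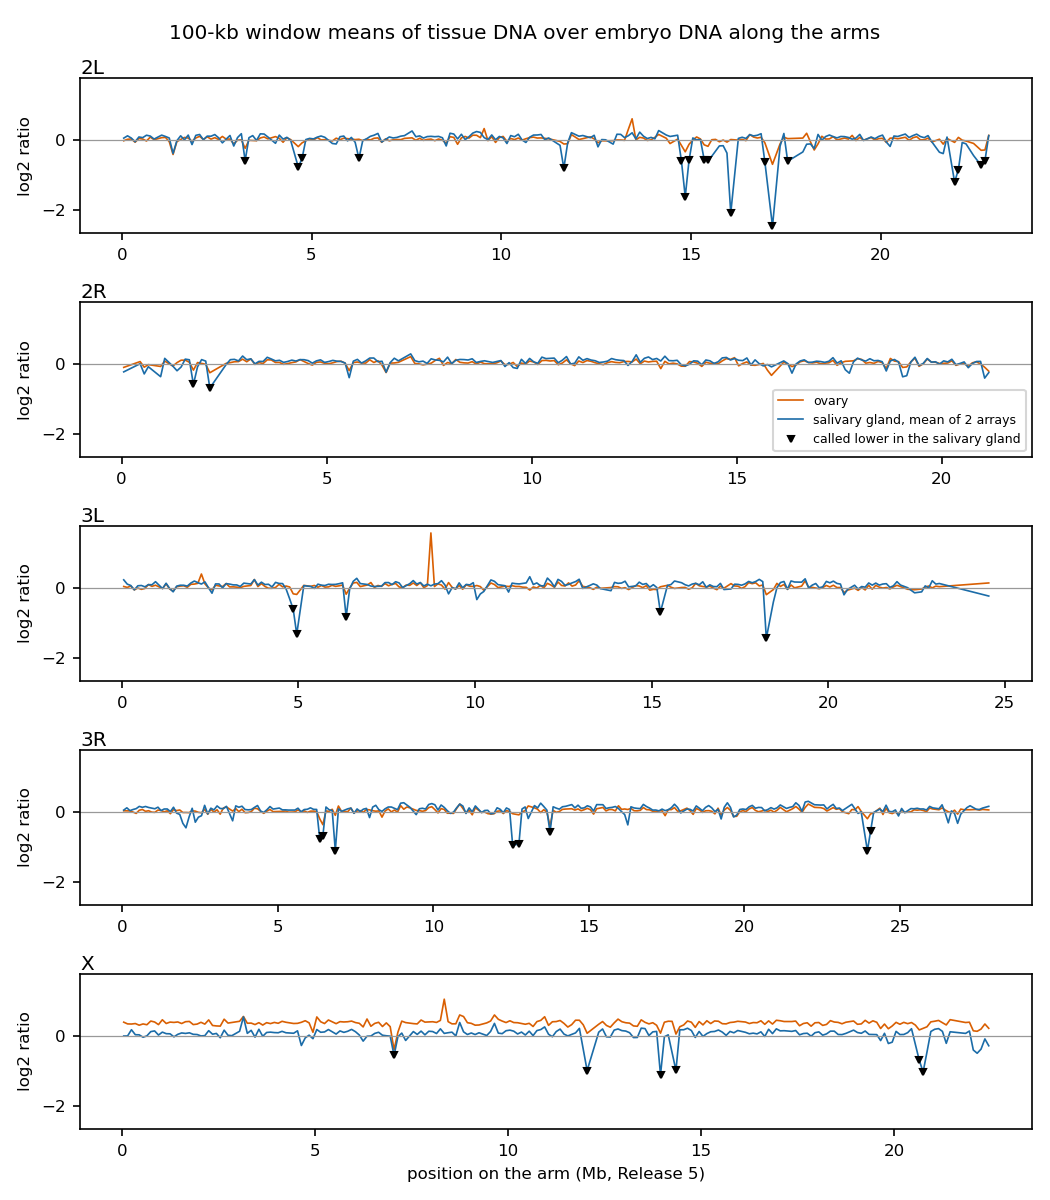
Mean log2 ratio of tissue over embryo DNA in windows of 100 kb (y axis) along the 5 large arms (x axis, Mb of Release 5), as lines for the ovary and for the mean of both salivary gland arrays. Triangles mark windows called lower in the salivary gland, among them the stretches of beat-IIIa on 2L and of abd-A and Abd-B on 3R, and the ovary line rises at the chorion genes of 3L and X.

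The glue genes, which encode the secreted adhesive of the larval salivary gland, were the raised group. Of 10 measured members 6 rose (6 adjusted over the list alone), with a list median of 0.94 (rotation test, adjusted p = 0.001, from the same smallest p). Sgs7 stood at 3.66 ± 0.56 and Sgs8 at 3.17 ± 1.97 (n = 2, adjusted p = 7.63e-05 and 0.0201). Sgs3, Sgs4 and Sgs5 stood at 1.86 ± 0.71, 1.54 ± 0.72 and 1.36 ± 0.99 (n = 2). The call of ng3 at 0.52 ± 0.27 (n = 2) ended when the distal arms were set to 0, and ng3 was called in the ovary too, at 0.69. The distal X as a whole, where ng3 lies, stood at 0.39 in the ovary. Sgs1 lay at -0.49 ± 0.00 (n = 2) without a call. All 6 raised genes were higher in replicate 2 than in replicate 1, and Sgs8 stood at 1.78 without replicate 2 and at 4.57 without replicate 1. The list median was 0.60 in replicate 1 and 1.45 in replicate 2. Among the other genes named by the rule, Obp99b, an odorant-binding protein gene, stood at 1.88 ± 1.19 and CG32710 at 1.92 ± 0.35 (n = 2). CG32710 was high in the ovary too, at 1.31, while Obp99b stood at 0.06 there. The 17 measured housekeeping genes had a median of -0.04 (rotation test, adjusted p = 0.014), which rose above 0 with normexp, with loess and in the authors' values. Against the distal arm genes they stood at -0.151, and at -0.080 with normexp, but at 0.0059 after loess and 0.030 in the authors' values. Of these genes only Act5C was called, at -0.85 ± 0.29 (n = 2), and that call ended in the authors' values (-0.41). Ald1 was the highest at 0.33 ± 0.06 (n = 2).

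In the test of 1637 windows of 10 kb, 21 windows were lower and 2 were higher in the salivary gland at an adjusted p under 0.05 and a log2 ratio of at least 0.5 in size. At the adjusted p alone, with no size asked, 98 windows were lower and 653 were higher, with the distal arms at 0.10 and 0.11 on the replicates. The excess of higher windows went with the centring, since these counts were 215 and 92 with the distal arms at 0 and 93 and 88 in the authors' values. The lowest window lay in the mitochondrial genome at -3.02, followed on the arms by the window of beat-IIIa and Gr36a at -2.45 (SE 0.05, n = 2). After loess the median of the mitochondrial genome was 0.62. Not all lower windows are particular to the salivary gland. The 4 on 2R stood at -0.40 to -0.42 in the ovary too, and that of Mob2 on 3L at -0.86. Others were not low there, as the window on 2L from 16000001 to 16010000, at -1.87 in the salivary gland and 0.02 in the ovary. The higher windows held Sgs5 at 0.78 ± 0.55 and Argk1 with Argk2 at 0.51 ± 0.19 (n = 2), and without replicate 2 neither passed the size. Their SE of 0.05 comes from the pooled spread and does not reflect the spread of these 2 windows. In the test of 1390 genes with at least 3 probes, 62 were lower and 1 was higher (Argk1 at 0.52 ± 0.25, n = 2), and at the adjusted p alone these counts were 120 and 290, but 91 and 1 with the distal arms at 0 and 101 and 15 in the authors' values. Windows with enough probes lie almost all on the arms, with 1 tested in each of 2LHet, 3LHet and Uextra. The ratio is tested against 0 and leaves out the spread of the embryo DNA itself, and all windows shared 1 pooled spread.

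The second comparison asks the same of ovary DNA. The chorion genes, which encode eggshell proteins and lie in known follicle cell amplicons, rose most. Of the 18 measured members of the eggshell list 13 rose (13 adjusted over the list alone), with a median of 1.49 (rotation test, adjusted p = 0.001, from the same smallest p). On 3L, Cp15, Cp16 and Cp19 stood at 3.44 (SE 0.08), 3.15 (SE 0.09) and 3.13 (SE 0.08), with adjusted p = 3.9e-05, 6.73e-05 and 4.83e-05. On the X, Cp38 and Cp36 stood at 2.08 (SE 0.08) and 2.04 (SE 0.09). Vm34Ca, a vitelline membrane gene on 2L, stood at 1.09, and CG13114 on 2L at 0.79. The ratio declined with distance from Cp15, with a median of 2.95 for genes 5 to 10 kb away, 1.44 for those 20 to 40 kb away and 0.14 for those 40 to 80 kb away. None of these chorion genes was called in the salivary gland, where Cp15 stood at 0.11 ± 0.04 and Cp36 at -0.03 ± 0.09 (n = 2). The list there had a median of 0.13 (rotation test, adjusted p = 0.637), with yellow-g2 lowest at -0.39 ± 0.14 and Femcoat highest at 0.61 ± 0.32 (n = 2). Femcoat was the 1 member called higher in the salivary gland, and that call ended in the authors' values (0.37).

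**Figure D3:**
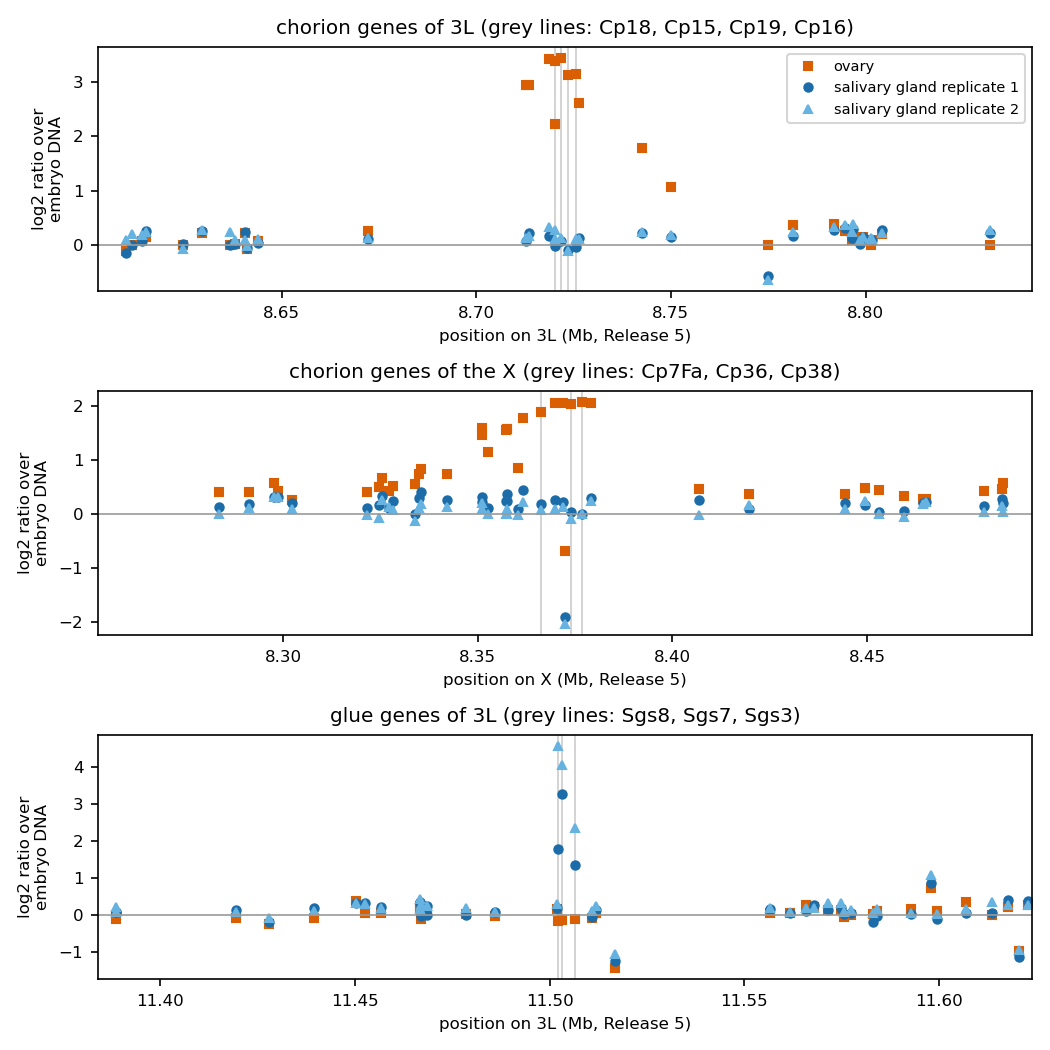
Log2 ratio of tissue over embryo DNA per gene (y axis) against position in Mb of Release 5 (x axis) around the chorion genes of 3L, the chorion genes of the X and the glue genes of 3L, with 1 point per gene and array and grey lines at the named genes. In the ovary the raised region extends beyond 20 kb from Cp15 and Cp38, and in the salivary gland the points of Sgs7, Sgs8 and Sgs3 stand above their neighbours.

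The X chromosome stood higher in the ovary than the autosomes did. Its median was 0.39 (3723 probes), and the X minus the autosomal arms gave 0.35 in the ovary, 0.07 in salivary gland replicate 1 and -0.07 in replicate 2. Among genes with at least 3 probes 23 rose in the ovary, of which 22 lay on the X, and CG13306 on 3L, in the region of the chorion genes, stood at 1.79. With normexp 4 genes rose, and with the distal arms at 0 only 1 did. In the Y list 11 entries were called lower in the ovary, with a list median of -3.68 (rotation test, adjusted p = 0.001, from the same smallest p), and adult females carry no Y. That median became -1.09 with normexp, -1.25 after loess and -2.49 in the authors' values, and in all 3 it lay above that of the salivary gland instead of below. Ppr-Y stood at -4.99 and ORY at -4.81. The assembled heterochromatin lay at -0.35 in the ovary, and its difference from the distal arms was -0.43, or -0.13 after loess. The dodeca satellite lay at -2.15 (-1.01 after loess), with 382 of 3285 probes called lower, and the AATAACATAG satellite at -1.71 (-0.61 after loess), with 41 of 42 called. This test of single probes called 0 of 67 simulated ovary changes of 2. The mitochondrial genome lay at -1.74, which became -0.45 after loess. The 5 tandem histone genes were not called, with a median of 0.17, which became -0.36 in the authors' values and 1.32 after loess.

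The remaining lists gave these ovary values. The pericentromeric list of chromosome 3 had 6 entries lower (6 adjusted over the list alone) and a median of -0.03 (rotation test, adjusted p = 0.178), with Pzl on U at -2.32 and scro at -0.60. The lists of chromosome 2, chromosome 4, Hox, histone and housekeeping genes had 0 members called. In the pericentromeric list of the X 2 genes were higher (3 adjusted over the list alone), among a median of 0.46. In the glue list 3 were higher, among them ng2 on the X at 0.74, and Sgs1 was lower at -0.67. Sgs7, raised in the salivary gland, stood at -0.13. The distal X as a whole stood at 0.39 in the ovary, so the values of the X list and of ng2 there include that level.

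In the window test of the ovary 4 windows were lower and 24 were higher, 18 of them on the X. At the adjusted p alone these counts were 30 and 266. The highest windows were those of CG6511 at 3.14 on 3L and of Cp7Fa and Cp7Fb at 1.70 on the X (SE 0.07), with the window of Cp15 next to the former. The lowest lay in the mitochondrial genome, and the lowest on an arm was that of CG7512, CG11714 and Mob2 on 3L at -0.86 (SE 0.07), where the salivary gland stood at -0.65. Of these genes only Mob2 was low, at -1.43 in the ovary and -1.15 in the salivary gland. The median of CG7512 and CG11714 was -0.01 in the ovary and 0.10 in the salivary gland. In the test of genes with at least 3 probes, added after the data were seen for the ovary, 23 were lower and 23 were higher, and with the distal arms at 0 these counts were 11 and 1. The lone ovary array was assumed to vary like the salivary gland arrays, so sizes carry more than the adjusted p. Past the size alone, 23 of these genes lay lower and 28 higher, which became 28 and 6 with the distal arms at 0. Setting the distal arms to 0 left 11 windows higher.

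The third comparison asks which sequences differ between the tissues, where the embryo DNA cancels. The assembled heterochromatin differed by -0.72 between the salivary gland and the ovary, and by -0.75 with the distal arms at 0. After loess it differed by -0.18, where the distal arms themselves differed by 0.12. The largest differences among genes with at least 3 probes were those of CR41610 at -2.36 (SE 0.09), Pzl on U at -2.35 (SE 0.08), Myo81F on U at -2.15 (SE 0.18) and CG41520 at -2.05 (SE 0.08), each lower in the salivary gland. Within the slide that the ovary shared with salivary gland replicate 1 these differences were -2.42, -2.37, -2.35 and -2.08. His3:CG31613 differed by -1.85 (SE 0.09, adjusted p = 0.00127), beat-IIIa by -1.40 (SE 0.08) and CG15279 by -1.45 (SE 0.13), with -1.90, -1.36 and -1.58 within the slide. After loess the differences of CR41610 and His3:CG31613 turned positive, at 0.15 and 0.86. IP10123 on 3L differed by -1.43 (SE 0.11) and CG13306, in the ovary amplicon of 3L, by -1.56 (SE 0.08). Of the list members, abd-A differed by -1.09 and Abd-B by -0.73 (adjusted p = 0.00335 and 0.0153), and the call of Abd-B ended after loess (-0.49).

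Chorion genes were lower in the salivary gland than in the ovary for 11 of 18 list members (12 adjusted over the list alone), with Cp15 at -3.33 (SE 0.10) and -3.36 within the slide. All 5 histone genes and 9 of 19 entries of the pericentromeric list of chromosome 3 were lower (5 and 10 adjusted over the list alone). No gene of the chromosome 2, chromosome 4 or housekeeping lists was called, though 2 of chromosome 2 passed when adjusted over the list alone. Sgs7 was the glue gene called higher, at 3.79 (2 adjusted over the list alone), with 3.40 within the slide. After loess the histone list stood higher in the salivary gland (1.99) than in the ovary (1.32). ORY on the Y was called higher in the salivary gland at 1.60, but stood at -0.64 with normexp, and the call ended after loess (0.03) and in the authors' values (0.22). It has 1 probe, and adult females carry no Y, so its ovary value (-4.81) does not measure a copy number. Of 13 genes with at least 1 probe that were higher in the salivary gland, 3 kept that direction with normexp, 11 with loess and 9 in the authors' values, and 3, 3 and 4 were still called.

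In the window test 27 windows were lower and 1 was higher in the salivary gland than in the ovary, and at the adjusted p alone 224 and 8. The latter counts became 51 and 51 with normexp and 57 and 295 after loess. Of the lower windows 16 lay on the X. The higher window was that of Sgs5, at 0.78 (SE 0.09 from the pooled spread), with 0.39 and 1.17 in the replicates and 0.01 in the ovary. Among the lower ones were windows raised in the ovary, as those of CG6511 and Cp15 at -2.94 and -2.92. In the test of genes with at least 3 probes 40 were lower and 0 were higher by limma, with 276 of 1390 at an unadjusted p under 0.05 in either direction. Within the shared slide 23 windows lay lower by the size threshold and 0 higher, with no test. With replicate 2 alone, on another slide, 50 windows lay lower by that size and 2 higher, so that the count rests in part on which replicate is set against the ovary. The slide cannot be told apart from replicate 2.

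The salivary gland arrays repeated each other with r = 0.865 (Spearman 0.626) over 1637 windows of 10 kb, where neighbouring windows are not independent. By rank, the ovary and salivary gland replicate 1, on the shared slide, agreed about as well (Spearman 0.601), and the ovary and replicate 2 less (0.220). By Pearson r both ovary pairs agreed less well than the salivary gland arrays, at 0.466 and 0.269. In the authors' values the pair on the shared slide agreed better by rank (0.690) than the 2 salivary gland arrays (0.550). By Pearson r that pair agreed less well there (0.527 against 0.860). Over windows of 100 kb the salivary gland arrays gave a Pearson value of 0.985 and a Spearman value of 0.742, and the standard deviation of the difference between the replicates was 0.08.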

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

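The contrast of brightness with the ratio over contig probes and the extra comparison of bright arm probes were tests chosen after the result was seen. A difference between the tissues in the ratio to embryo DNA, tested with limma, marked 3 counts for a closer look. In windows of 10 kb, 27 were lower and 1, that of Sgs5, was higher in the salivary gland than in the ovary, and among genes with at least 3 probes 40 were lower. Of the 27 lower windows 16 lay on the X. The tissues differ in stage and in cell types, ovaries come from females only, and the sex of the larvae is not given. The lower windows also hold gains in the ovary. Those of CG6511 and Cp15 on 3L differed by -2.94 and -2.92, with the salivary gland at 0.20 and 0.08. The X minus the autosomal arms was 0.35 in the ovary against 0.07 and -0.07 in the replicates, a difference that enters every window of the X. The lower count is therefore not all loss in the salivary gland. A further biological difference stays open for each count and was not tested apart from stage, cell types and sex.

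The glue genes were higher in the salivary gland, and the 6 raised ones had a median of 1.70 there. If DNA amplification of their region were the source, genes within 10 kb should be raised by at least 0.5, as the 17 neighbours of raised chorion genes in the ovary were with a median of 1.59. The 9 neighbours of the glue genes had a median of 0.254. By the bound set beforehand only a median under 0.25 was to argue against amplification, so by that bound alone this value cannot decide. It is centred on the median probe, where the distal arms sat at 0.10 and 0.11 on the replicates, so it holds that offset. The 9 neighbours ranged from -0.147 to 0.439, and none reached 0.5. These values argue against a rise of 0.5 across 10 kb on each side, but not against a shorter stretch. RNA or cDNA of the tissue in the labelled DNA may be another source, but 4 vitelline membrane genes, strongly expressed in egg chambers, stood only 0.128 above the autosomal arms in the ovary, within the bound set beforehand against it. That bound assumed equal carry-over in separate DNA preparations, a point raised after the value was seen. The raised glue genes differed between the gland replicates by a median of 1.01, against a standard deviation of 0.177 for all genes. The 6 genes were picked for their high values, so this difference is a description and decides nothing. RNA carry-over and a short amplified or extra replicated stretch cannot be told apart here.

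Low ratios in the salivary gland went with a bright embryo signal, as for satellites, histone genes and mitochondrial DNA. A bias set by brightness alone is argued against by heterochromatin probes with an embryo signal in the middle 50% of distal arm probes, which stood -1.12 from arm probes of that brightness (103 and 10949 probes, -1.03 and -1.08 in the replicates). The brightest 1% of distal arm probes had a median of -0.08, and contig probes at least as bright had -4.25, though many of the latter are brighter still. Over contig probes the Spearman correlation of embryo signal and ratio was -0.697, but the embryo signal is the denominator of the ratio, so the sign is partly built in and under-represented repeats stay open. For the bright sequences themselves the number of copies was not measured. Loess turned the histone and most mitochondrial values positive, but it removes a change shared by most bright probes, so it cannot settle their direction. The histone list median stayed low with normexp (-1.53) and in the authors' values (-2.21), as did the mitochondrial median (-2.85 and -3.51).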

How the results depend on the processing

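Windows of 100 kb, gene counts without a replicate, gene differences with the distal arms at 0 and the test of ovary genes and the alternatives for it, medians of lists, list differences from the arms, contig series and satellites were tests chosen after the data were seen. Counts are given as lower and higher, for the salivary gland against embryo DNA, the ovary against embryo DNA and the salivary gland against the ovary in this order, and the cause of a change was not tested unless stated. Before any alternative the window counts were 21 and 2, 4 and 24, and 27 and 1. With fewer windows tested (5 kb) they were 10 and 1, 4 and 10, and 10 and 0, and with at least 10 probes 3 and 0, 2 and 0, and 3 and 0. With more units tested, at least 3 probes gave 114 and 7, 34 and 64, and 105 and 2, and single probes gave 27716 and 2360, 6548 and 469, and 18896 and 237. Windows of 100 kb gave 73 and 1, 23 and 9, and 64 and 1. A size of at least 1, stricter by construction, gave 6 and 0, 2 and 6, and 10 and 0. Loess gave 7 and 127, 2 and 28, and 14 and 69. Normexp without loess gave 10 higher in the ovary and 16 lower against the ovary. The authors' values gave 1 higher in the salivary gland, 7 lower in the ovary and 0 higher against the ovary. The distal arms at 0 left 1 higher in the salivary gland and 11 higher in the ovary. The median of the probes gave 9 lower and 1 higher in the salivary gland, and windows of 20 kb gave 1 higher.

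Past the size alone, leaving out either salivary gland replicate gave 0 to 3 windows higher than embryo DNA, and 23 to 50 lower and 0 to 2 higher than the ovary, with 0 higher within the shared slide. For genes these ranges were 0 to 4 higher than embryo DNA, and 51 to 101 lower and 0 to 1 higher than the ovary. The larger values came without replicate 1. With the distal arms at 0, 72 genes lay lower than the ovary by the size, against 62 at first, though fewer were called.

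Genes lower and higher in the salivary gland against embryo DNA, 62 and 1 at first, became 26 and 187 with loess, 1042 and 66 with at least 1 probe and 8 and 0 with at least 5 probes. The higher count became 4 with normexp, 0 in the authors' values and 0 with the distal arms at 0. Against the ovary, 40 and 0 became 23 and 111 with loess and 733 and 13 with at least 1 probe, and the lower count became 2 with at least 5 probes and 18 with the distal arms at 0. In the ovary, 23 and 23 became 13 and 40 with loess, 11 and 1 with the distal arms at 0, 508 and 501 with at least 1 probe and 1 and 2 with at least 5 probes, and the higher count became 4 with normexp. Heterochromatin minus distal arms, -1.18 at first, became -1.09 with normexp, -0.43 with loess and -1.34 in the authors' values. Stretches of called windows became 48 lower and 1 higher in windows of 100 kb, and the correlation of the replicates became 0.915 with loess.

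These directions turned. The housekeeping median became 0.058 with normexp, 0.19 with loess and 0.046 in the authors' values, where the level of the arms moved too. Its difference from the distal arm genes, -0.151 at first, kept its direction with normexp (-0.080) but became 0.0059 with loess and 0.030 in the authors' values, where that of the ribosomal protein genes became 0.052. With loess COX1 became 1.01, COX3 1.28, ND4 0.49, LD48059 0.21, CR41610 0.54, uex 0.58, His1:CG31617 2.85, His2A:CG31618 1.62, His2B:CG17949 1.99, His3:CG31613 2.40 and His4:CG31611 1.503, and against the ovary CR41610 became 0.15 and His3:CG31613 0.86. With normexp ORY became -0.64 against the ovary. Of the region medians, loess gave 1.44 for 2LHet, 0.62 for M, 0.46 for Uextra and 0.107 for the proximal 1 Mb of 2L in the salivary gland, and 0.25 for Uextra in the ovary. The authors' values gave -0.14 for the contig series in the salivary gland, -0.13 in the ovary, -0.044 for the proximal 1 Mb of 2R and -0.056 for chromosome 4 in the ovary, and the distal arms at 0 gave -0.055 and -0.033 for the last 2. Medians near 0 turned too, among them XHet (0.18), the proximal 1 Mb of X (0.060) and 2LHet in the ovary (0.25) with loess, and the proximal 1 Mb of 2L (0.019) and of X (0.0086) with normexp. Loess sets the ratio at each brightness to a common level, so it removes a change shared by most bright probes, whatever its source. Of 82 gene values tried, 76 kept direction and side of the threshold in the authors' values, 79 with the distal arms at 0, 77 with normexp and 63 with loess, where 13 turned. Of the values that answer a comparison, 66 stayed and 88 moved. A count was taken to move when it changed by a factor over 1.5, or to or from 0. Many settings tested other numbers of units, and filters that removed almost no probe were among those tried. The tally therefore does not measure robustness.

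The filter on dim spots and the filter on shared sequence removed almost no probe of the window and gene fits, so they say nothing on the stability of these. The filter on dim spots cut the contig series from 28262 to 25609 probes. Signal over background did not limit most spots, since at least 97.7% were well above it in either channel. In simulated data at most 43.9% of the windows changed by 0.5 were called and at least 98.5% of those changed by 1. A change of 0.5 lies on the size threshold itself, so many estimates fall short of it by noise alone. The share at 0.5 is therefore set largely by that threshold. Among genes with at least 1 probe 3.03% of changes of 0.5 were called between the tissues and 10.6% in the ovary, and of single probes changed by 2 there 0 of 67 in either test. In the simulated data 0 windows were called wrongly, but 14 to 19 genes with at least 1 probe and 6 to 52 probes were. All 3 simulated arrays were independent noise around 0 with the spread of the salivary gland replicates. These counts therefore say nothing on a slide effect, a centring offset or the ovary's own spread. In the real windows the standard deviation of the difference was 0.10 between the replicates, and 0.20 and 0.25 between the ovary and replicates 1 and 2. No paired analysis was possible because the only replicate number shared by the tissues does not stand for a common animal or batch of animals.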

Other observations

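The comparison of ribosomal protein genes and the naming of further stretches were tests chosen after the first values were seen. On 2L the window from 16000001 to 16100000, with beat-Ia, beat-Ic and BicC, lay at -2.09 ± 0.05 (n = 2) in the salivary gland and at 0.02 in the ovary. The further values of this paragraph are for the salivary gland. On 3L the stretch from 4800001 to 5000000, with Con, Dhc64C and Dnah3, lay at -0.96 ± 0.02 (n = 2), and the window from 18200001 to 18300000, with the cell death gene grim, at -1.44 ± 0.12 (n = 2). On 3R the window from 6800001 to 6900000, with side-VI, lay at -1.11 ± 0.05 (n = 2). The 2L stretch from 15300001 to 15500000 holds the Snail family genes esg, wor and sna and lay at -0.57 ± 0.00 (n = 2). On the X the window from 12000001 to 12100000, with Ten-a, lay at -0.99 ± 0.25, that from 13900001 to 14000000, with the Stellate genes Ste:CG33246, Ste:CG33240 and Ste:CG33238, at -1.12 ± 0.10, and that from 14300001 to 14400000, with dpr8, at -0.99 ± 0.03 (n = 2).

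In the ovary, copies of the Y-linked Su(Ste) repeat lay among the lowest, with Su(Ste):CR42418 at -5.42 and Su(Ste):CR42444 at -5.39. The stretch around Vm34Ca on 2L showed the gradient of the larger amplicons on a smaller scale, with ovary medians of 1.07 for genes within 5 kb, 0.70 at 10 to 20 kb and 0.11 at 40 to 80 kb.

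The housekeeping genes of the arms had a low median in the salivary gland, and the tests of it were written after that median was known. If RNA or cDNA of the embryos in the reference DNA were the source, other strongly expressed genes should be low too. The 87 ribosomal protein genes of the arms stood -0.153 from the distal arm genes, with -0.089 in replicate 1 and -0.22 in replicate 2, against the -0.1 asked of both, and at 0.07 in the ovary against the same reference. Under-replication of the regions is argued against by the 466 genes within 10 kb of them, which stood -0.00998 from the distal arm genes. Set against the distal arm genes, the ribosomal protein genes stood at -0.120 with normexp and -0.123 after loess but at 0.052 in the authors' values, so RNA in the reference may be a cause but stays open, and no biological explanation was tested.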
